A study of Mus musculus with 6 samples.

How the data were processed

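The series holds ChIP-seq libraries of 2 cell lines, mK3 and mK4, with 1 library each for an H3K4 antibody, an H3K27 antibody and input. Per the labels, the lines are immortalized E11.5 metanephric lines of strain CD1, the H3K4 antibody carries the catalogue number ab8898, the H3K27 antibody carries 39535, and the libraries were made by a commercial service on an Illumina pipeline. Groups were taken from the sample titles, and each of the 6 groups has 1 library.

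Each deposited file lists 22088 gene rows with a chromosome, a gene symbol, an exon length, a read count and an RPKM value, in the same order in all 6 files. Per the file headers, the deposited counts are whole reads per gene set against exon length, and the authors' RPKM is that count per exon kilobase, scaled to the library's reads. The deposited RPKM values were recomputed from the counts, exon lengths and each file's own count total, which they matched, so the totals are sums over exons and not the number of sequenced reads. The exon length per gene was deposited by the authors in a further column. Input reads per exon kilobase were about the same over genes with short and long introns (between 4.86 and 5.34 in mK3 over 5 equal groups of genes ranked by the ratio of gene span to exon length), as for reads counted in exons. Signal at promoters upstream of the first exon is then not in these counts. The genome build was mm9, per the submitters' processing notes. The aligner, read length and any removal of duplicate reads are not given in the sources used here. No peak positions were used.

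Counts were used as deposited, and the RPKM values only for the check of totals. Where a symbol had several rows (137 symbols, 151 rows), the row with the highest mean over the 4 ChIP libraries was kept, which left 21937 genes. Counts were scaled to equal library totals of 513622, the mean of the 6 totals, and ratios were formed on log2 of the scaled count plus a pseudocount of 5. This scale understates differences of genes with few reads. A gene was called marked when its ChIP value was at least 2-fold its own line's input, and higher or lower in mK4 when it was marked in at least 1 line and its ratio between the lines was at least 2-fold. Folds printed with intervals are ratios of read shares without pseudocount, with an exact Clopper-Pearson interval for the share of reads that fell to 1 of the 2 libraries. With 1 library per group no test was made, and no count model such as a dispersion fit was used. To show what counting error alone gives, 100 sets of Poisson counts were drawn from the pooled rate of the libraries compared. For changes, the observed inputs were kept in these draws.

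The 25 gene lists were fixed before the data were examined, together with the groups and rules. The median of each list was placed among 10000 random lists matched on mean level in 10 bins, drawn with replacement within bins, as a description of these libraries. Percentiles below 2.5 or above 97.5 are called outside the central 95%. Named genes are the 12 with the largest ratio in each direction for each mark among genes that passed the rule and had a mean scaled count at or above the median of marked genes (21.4 for H3K4 and 24.5 for H3K27), leaving out clone-named, small RNA and sex chromosome genes. Of these, 1 gene is not reported here and was not replaced. Up to 4 members of each list per mark with the largest absolute ratio, 16 genes fixed by name, and up to 6 examples of each class of genes with both marks in mK3 were added. Gene symbols were matched to a RefSeq gene table of assembly GRCm38.p6 for the order of neighbouring genes only, 19325 by symbol and 2290 by synonym on the same chromosome, with 322 unmatched.

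Several steps were chosen after the data were seen. The log2 input ratio between the lines, summed over the 10 neighbouring genes on each side with the gene itself left out, was subtracted from each gene's ratio. A window of 5 neighbours was tried first and is kept as an alternative. It also picked out short runs of genes, after which the window was widened, runs were required to hold at least 10 genes with a neighbour ratio of at least 1.5 on the log2 scale, and their ends were trimmed to genes whose own input ratio was at least 1. A background from exon length, the removal of the chromosome 15 run and of chromosomes 3, 7, 14 and X, and a random split of the input reads between the marks were also added then. So were 100 sets of Poisson counts for the correlation of input with mark differences, drawn with the neighbour input ratio as the difference between the lines in all 3 kinds of library and with that ratio computed anew in each set. For the chromosome 15 run, the fold of the ChIP libraries replaced the input fold as the test of copy number, because the run had been chosen on its input. For the Hoxa genes, the ratio of input to H3K4 density replaced the input density alone, because their H3K4 density was also high. Genes of the closing paragraphs outside the named-gene rule (Hoxa9, Hoxa10, Hoxa11, Hoxa11as, Malat1 and Neat1) were chosen after their values were seen. The alternatives set before the data were examined were other pseudocounts (2.5 and 10), other fold thresholds (1.5 and 3), scaling to equal medians, quantile normalization, median centring, a filter on genes below the 25th percentile, the mean of a gene's rows, and subtraction of each gene's own input ratio.

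After the data had been analysed, the calling was tested on simulated data over 21937 genes with 200 marked genes changed. For H3K4, 23.9% of 2-fold, 47.8% of 3-fold and 66.7% of 4-fold changes were recovered, with 22 calls among unchanged genes. For H3K27, the shares were 19.4%, 62.7% and 71.2%, with 49 calls among unchanged genes. Of 1000 simulated lists of 20 genes with no shift, 51 fell outside the central 95%. The first 100 of them, run alone at first, gave 13, after which the number was raised to 1000. With a shift of 0.50 on the log2 scale, 969 lists lay above it. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 was used.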

Results

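Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to compare 2 immortalized mouse cell lines of the E11.5 metanephric kidney, mK3 and mK4, both labelled as strain CD1. In ChIP-seq, chromatin fragments are pulled down with an antibody against a histone modification and the recovered DNA is sequenced, so that read counts over a gene rise with the amount of the modification there. The series asks how histone methylation relates to the fate of nephron progenitors, the cells that give rise to the filtering units of the kidney. Each line had 1 library with an antibody labelled H3K4, 1 with an antibody labelled H3K27 and 1 input library of chromatin without pull-down. Methylation at H3K4 is generally found at active promoters, and trimethylation at H3K27 marks genes silenced by Polycomb proteins, but the labels do not state the degree of methylation that either antibody recognises. The summed exon counts were 595305 for mK3 H3K4, 714011 for mK4 H3K4, 593079 for mK3 H3K27, 481235 for mK4 H3K27, 311409 for mK3 input and 386695 for mK4 input. The median count per gene row lay between 10 in the mK3 input and 23 in the mK4 H3K4 library. There were no replicates, so no difference below has a replicate check and no p-value is given. Intervals are 95% counting intervals, which cover counting error only and understate the true error.

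The H3K27 libraries lay over input at genes of lineages foreign to the kidney. Of 38 transcription factor genes of neural, endodermal, cardiac and muscle lineages, 23 were marked by H3K27 in mK3 and 17 in mK4, where a marked gene had at least 2-fold its input. The median of this list over input was 1.28 on the log2 scale in mK3 and 0.76 in mK4, a level that 0 of 10000 level-matched random lists reached in either line. In mK4 the loop of Henle and distal tubule genes had a median of 0.78. No ribosomal protein gene was marked by H3K27 (0 of 80 in each line), whereas H3K4 marked 12 of the 80 in mK3 and 15 in mK4. The H3K4 median of the ribosomal protein genes over input was 0.41 in mK3 and 0.30 in mK4, reached by 0 and 1 of the 10000 random lists. The housekeeping list did not stand out in this way. Its H3K4 medians over input were 0.05 in mK3 and -0.01 in mK4 (percentiles 73.2 and 58.1), with 3 and 2 of 27 members marked. Over all 21937 genes, H3K4 marked 1083 genes in mK3 and 810 in mK4, and H3K27 marked 2251 in mK3 and 1988 in mK4. Most of these calls were made in 1 line only. Of 1715 genes marked by H3K4 in at least 1 line, 178 were marked in both, where independent sets would share 40. For H3K27, 625 of 3614 genes were marked in both lines, where independent sets would share 204. Counting noise alone gave a mean of 313 and 179 marked genes in mK3 and mK4 for H3K4 and of 314 and 226 for H3K27. The observed counts of marked genes depend on the background. With exon length in place of the input, an alternative chosen after the data were seen, H3K27 marked 523 genes in mK3 and 771 in mK4. H3K4 then marked 1260 in mK3 and 1368 in mK4, so that for both marks the line with more marked genes changed.

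Genes of differentiated kidney segments and of other tissues were also among those with H3K27 over input. For comparison, H3K27 marked 10.3% of all genes in mK3 and 9.06% in mK4. The list counts are scored against the input, and the total counts above depended on that background. Proximal tubule genes were marked by H3K27 at 5 of 16 members in mK3 and 6 in mK4, and by H3K4 at none in either line. Genes of the loop of Henle and distal tubule were marked by H3K27 at 4 of 14 members in each line. Blood and immune genes (3 of 14 in each line) and endothelial genes (3 of 14 in each line) were marked as well. Epithelial junction and keratin genes were marked by H3K27 at 9 of 24 members in mK3 and 4 in mK4, ureteric bud and collecting duct genes at 6 of 18 and 2 of 18, and podocyte genes at 3 of 14 and 2 of 14. Wnt ligands and antagonists had 8 of 24 members marked by H3K27 in mK3 and 7 in mK4, and the Notch pathway 2 of 17 and 6 of 17. Renal stroma genes (0 of 18 and 1 of 18), mesenchymal genes (0 of 20 and 1 of 20), chromatin regulators (0 of 30 in each line) and housekeeping genes (1 of 27 and 0 of 27) were rarely marked. Nephron progenitor genes were marked by H3K27 at 2 of 20 members and by H3K4 at 3 of 20 in each line. Olfactory receptor genes, included as a background list, also passed the rule at 177 of 1102 members in mK3 and 110 in mK4, and vomeronasal receptor genes at 37 of 328 and 19 of 328. As for the non-renal factors, 0 of 10000 random lists reached the olfactory receptor median over input in either line.

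**Figure D1:**
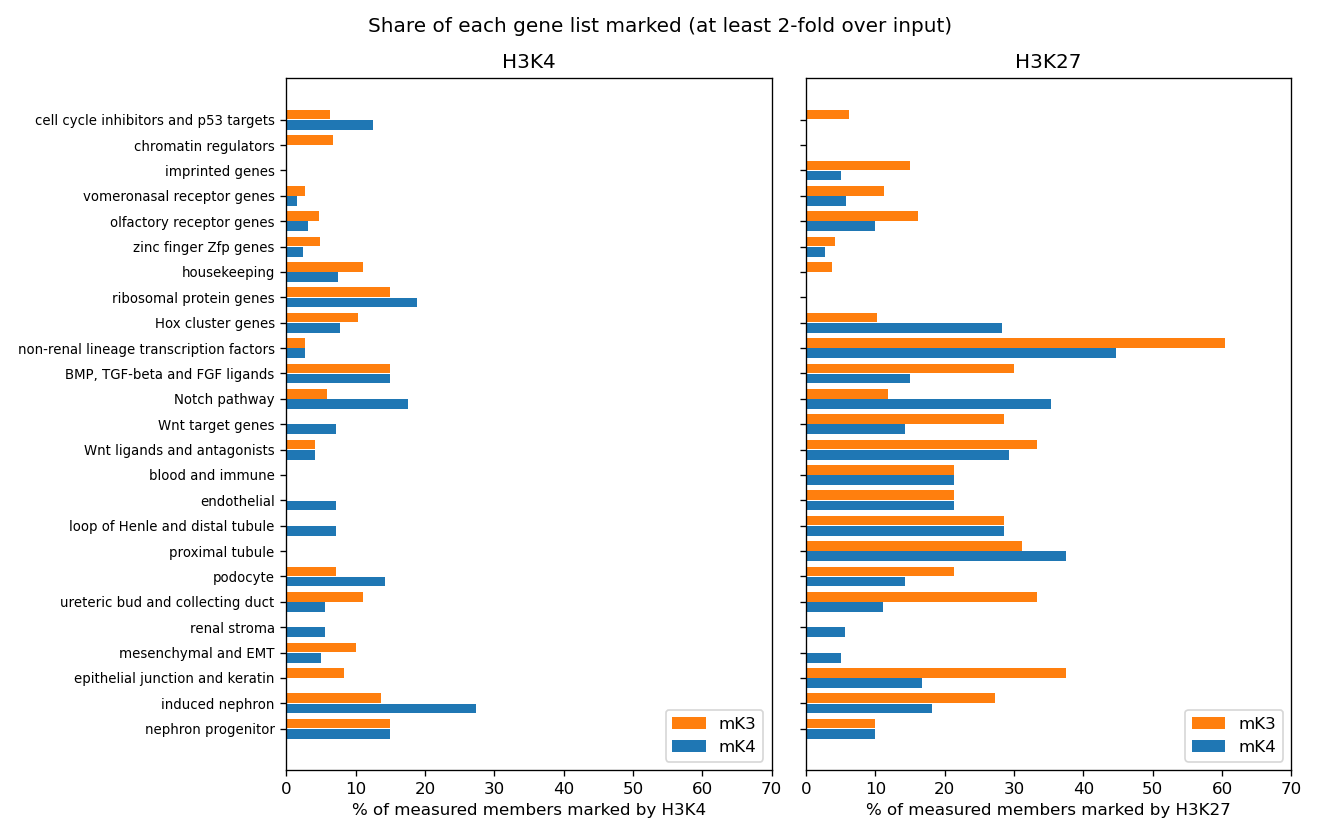
Percent of the measured members of each fixed gene list that were marked (at least 2-fold over input) by H3K4 (left) and H3K27 (right), with mK3 in orange and mK4 in blue and 1 library per bar. The list of non-renal lineage transcription factors has the highest H3K27 share, 60.5% in mK3 and 44.7% in mK4, and the ribosomal protein genes have none.

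Some genes held both marks. In mK3, Wnt7b, a Wnt ligand of the ureteric bud, had 38 H3K4 reads, 99 H3K27 reads and 8 input reads. Wnt1 had 26, 66 and 5 reads in the same order, and Esrp1, an epithelial splicing regulator, had 35, 64 and 7. Both marks were found at 306 genes in mK3 and 171 in mK4, but at 65 and 187 with exon length as background, so which line had more depended on the background. Independent sets of the same sizes would share 111 and 73 genes, and counting noise in 3 libraries with equal rates gave 121 and 60. Of the 306, 30 were olfactory receptor genes and 8 vomeronasal receptor genes. The fixed induced nephron and epithelial junction lists had 2 members each among the 306, and no other fixed list had more than 1. Of the 306 genes in mK3, 3 held both marks in mK4, 8 held H3K4 only, 52 held H3K27 only and 243 held neither. Among all genes in mK4, 0.78% held both marks, 3.69% held H3K4 and 9.06% held H3K27, with or without the other mark. The 306 genes lay near the shares of all genes for both marks and for H3K4, and above that for H3K27. Hes5, a Notch target, was among the 3 with both marks in both lines. Psmb2 was among those with H3K4 only, Sox2, Bmp7 and Wnt1 were among those with H3K27 only, and Irx3 and Wnt7b were among those with neither. Both marks were scored against the same input, and several of these genes had few input reads in mK3 (1 for Sox2, 3 for Irx3 and 0 for Bmp7 and Hes5). When the input reads were split at random so that each mark had its own part, the overlap was 331 genes against 245 for independent sets in mK3, a ratio of 1.35, and 199 against 170 in mK4, a ratio of 1.17.

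Summed over whole chromosomes, the 3 kinds of library differed between the lines in the same way. The input share of chromosome 3 was 1.84-fold higher in mK4 (1.8 to 1.88), that of chromosome 7 was 1.54-fold higher (1.51 to 1.58) and that of chromosome X was 1.49-fold higher (1.45 to 1.54), while chromosome 14 had a ratio of 0.644 (0.628 to 0.66). The H3K4 and H3K27 ratios were 1.86 and 1.89 on chromosome 3, 1.55 and 1.44 on chromosome 7 and 0.644 and 0.641 on chromosome 14. Input ratios were not even within chromosomes. On chromosome 5 (0.912), the summed input of the 10 neighbours on each side had a log2 ratio of 1.28 at Actb and Lfng. On chromosome 4 (0.928) it was -0.95 at D4Bwg0951e. Leaving out chromosomes 3, 7, 14 and X and the run described next therefore does not remove all such differences. On chromosome 15, a run of 35 consecutive measured genes from Nipbl to Cdh9 had an input share 8.67-fold higher in mK4 (8.11 to 9.28), with 8.49-fold for H3K4 (8.08 to 8.93) and 8.68-fold for H3K27 (8.28 to 9.11). Cdh6, a cadherin of the early nephron, lies in this run, and its 20 H3K4 reads in mK3 and 421 in mK4 stood beside 9 and 259 input reads. It was not marked in either line. Of the 93 genes with higher H3K4 in mK4, 56 lay on chromosomes 3, 7 and X, as did 118 of the 195 with higher H3K27.

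**Figure D2:**
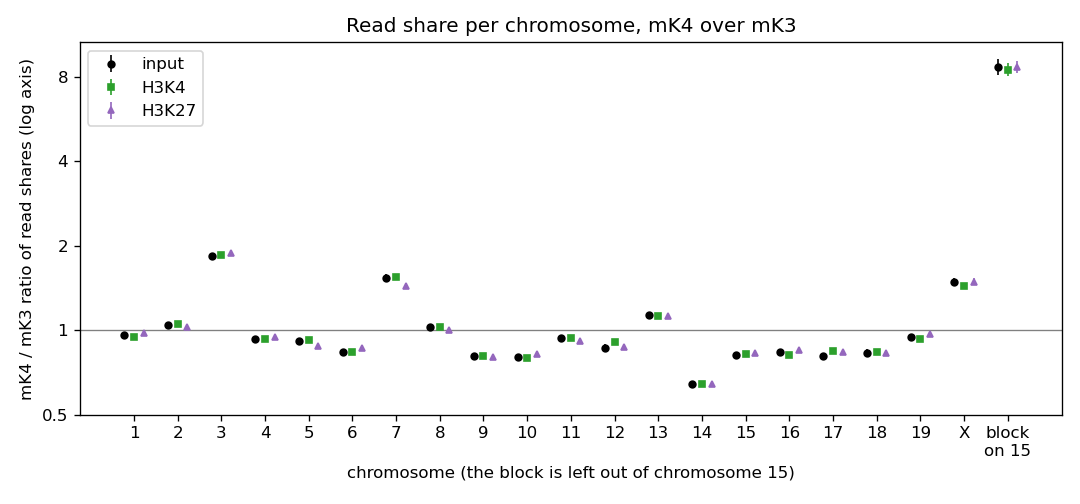
Ratio of read shares, mK4 over mK3, for the genes of each chromosome in the input (circles), H3K4 (squares) and H3K27 (triangles) libraries, on a log axis with 95% counting intervals, with 1 library per line and kind. The 3 ratios lie close together on each chromosome, with chromosomes 3, 7 and X above 1, chromosome 14 at 0.644 and the run of 35 genes on chromosome 15 at 8.67 in the input.

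The comparison of H3K4 between the lines asks which genes carry different amounts of the mark. Higher H3K4 in mK4 was found at Irx1, an Iroquois transcription factor of the nephron, with 8 reads in mK3 and 75 in mK4 (7.82-fold, 3.77 to 18.8). Nog, which encodes the BMP antagonist Noggin, had 28 and 149 reads (4.44-fold, 2.95 to 6.9), Sox11 had 103 and 422 (3.42-fold, 2.75 to 4.28), Irx5 had 35 and 141 (3.36-fold, 2.31 to 5.01) and Bcl2l1, a survival gene of the BCL2 family, had 35 and 163 (3.88-fold, 2.68 to 5.77). Lower H3K4 in mK4 was found at Twist1, a transcription factor of mesenchymal cells, with 100 reads in mK3 and 1 in mK4 (120-fold lower, 21 to 4784). The posterior HoxC genes Hoxc11 (53 and 6 reads, 10.6-fold lower, 4.56 to 30.2), Hoxc10 (81 and 19, 5.11-fold lower, 3.07 to 8.93) and Hoxc13 (75 and 25, 3.6-fold lower, 2.26 to 5.91) were lower too. So were Ptx3 (4.67-fold, 2.79 to 8.19), the membrane metalloproteinase gene Mmp14 (3.56-fold, 2.31 to 5.62), Klf2 (2.91-fold, 1.81 to 4.78) and Snai1, a transcription factor of epithelial-mesenchymal transition (2.4-fold, 1.37 to 4.33).

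Among genes marked in at least 1 line, H3K4 was at least 2-fold higher in mK4 at 93 and at least 2-fold lower at 86, where counting noise alone gave means of 9 and 9. Centring the ratios on their median gave 110 and 63, and choosing the marked genes against exon length gave 311 and 106. In the 2 inputs, 362 of the same 1715 genes were at least 2-fold higher in mK4 and 221 lower, a comparison in which a low input is also part of what made a gene marked. After the input ratio of the 10 neighbouring genes on each side was subtracted, a step chosen after the data were seen, 84 genes were higher and 81 lower, of which 34 and 37 were also called before. Irx1, Irx5, Nog, Sox11, Bcl2l1, Twist1, Hoxc10, Hoxc11, Ptx3, Mmp14, Klf2, Cd164 and Snai1 passed in both forms, as did Stard5. Acp6, Gclm, Lef1 and Scnm1 on chromosome 3, Ranbp3l in the chromosome 15 run, and Hoxc13, Ccdc65, Ei24, Tdrd3 and D4Bwg0951e no longer passed after neighbour subtraction. Of the 11 ranked genes with higher H3K4, 6 lay on chromosome 3 or 7 or in the run. With each gene's own input subtracted, 5 of these 11 and 9 of the 12 ranked lower genes passed. The log2 ratios of the others were 0.99 at Sox11, 0.96 at Acp6, 0.91 at Gclm, 0.63 at Bcl2l1, 0.21 at Lef1, -1.81 at Ranbp3l, -0.94 at Mmp14, -0.38 at D4Bwg0951e and -0.20 at Ptx3. Ptx3 had 17 and 4 input reads, and its H3K4 lay 2.28-fold over input in mK3 and 2.57-fold in mK4. Without the run and chromosomes 3, 7, 14 and X, 36 genes were higher and 69 lower.

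As groups, genes induced at the start of nephron formation lay higher in mK4 for H3K4. The median of the 22 genes was 0.57 on the log2 scale (reached by 0 of 10000 level-matched random lists), with 2 of 22 passing the gene rule, Irx1 and Lef1. The inputs moved the same way at 0.35 (percentile 99.5). The median was 0.44 (again reached by 0 lists) with neighbour input subtracted and 0.22 (percentile 93.0) with each gene's own input subtracted. Mesenchymal genes lay lower in mK4, with a median of -0.46 (percentile 0.1, inputs 27.1) and with Twist1 and Snai1 passing, and at -0.24 (percentile 1.3) and -0.24 (percentile 6.8) under those subtractions. The 39 Hox genes had a median of -0.45 (percentile 0.0), with 3 lower and 1, Hoxb7, higher, but their inputs lay at -0.58 (percentile 0.0). Their H3K4 median was -0.04 (percentile 26.1) with neighbour input subtracted and 0.17 with own input subtracted. Neighbours of a Hox gene include other Hox genes, so that neighbour input is not independent of the list. For Hoxa genes they include Hoxa10, Hoxa11 and Hoxa11as, whose high inputs (322, 347 and 302 reads in mK3, 175, 245 and 325 in mK4) are described below. Renal stroma genes lay at -0.42 (percentile 0.5), with inputs at -0.41, none passing the rule, and at -0.20 (percentile 4.7) and -0.07 (percentile 35.6) with neighbour and own input subtracted, but at -0.26 (percentile 1.8) with 5 neighbours. The nephron progenitor list lay at -0.17 (percentile 17.8) with 1 member, Hoxc11, lower, and at -0.09 (percentile 18.1) and 0.06 with neighbour and own input subtracted. The Notch pathway (0.29, percentile 98.4, and 95.8 and 95.7 with neighbour and own input subtracted, but 98.7 with 5 neighbours) had no member past the rule, and the ribosomal protein genes (0.15, percentile 98.5, and 75.8 and 77.3 in the same order) had 1, Rpl39, with 2 and 12 reads (5-fold, 1.11 to 46), which did not pass with neighbour input subtracted. The 332 Zfp genes had a median of 0.06, reached by 2 of 10000 random lists, with none past the rule, inputs at 0.08 and percentiles 72.2 and 79.5 with neighbour and own input subtracted. Olfactory receptor genes lay at -0.04 (percentile 0.0), at 0.00 (percentile 50.0) with quantile normalization at 0.12 (percentile 98.5) with neighbour input subtracted and at 0.02 (percentile 99.8) with own input subtracted. The other lists had H3K4 percentiles inside the central 95%, though with 5 neighbours the epithelial junction list (0.37, percentile 99.5) and the endothelial list (0.34, percentile 97.7) lay outside. Among single genes fixed in advance, Pax2 had 4 H3K4 reads in mK3 and 26 in mK4, Pax8 20 and 64, Wnt4 1 and 8, Wt1 10 and 23, Eya1 20 and 50, Six2 28 and 13, Osr1 36 and 21, Sall1 35 and 46, Jag1 49 and 77, Cdh1 39 and 50 and Foxd1 95 and 131. None of these passed the gene rule for H3K4, and of them Foxd1 in mK4 was marked by H3K4. The housekeeping genes Actb (102 and 214 H3K4 reads) and Gapdh (16 and 9), also fixed by name, were marked by H3K4 in neither line. These reads are not scaled to library totals, and the inputs could differ as well. Input reads were 20 and 45 at Eya1, 28 and 58 at Actb and 8 and 2 at Gapdh. With own input subtracted, the H3K4 log2 ratios of these 3 genes were 0.11, 0.09 and 0.54.

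The comparison of H3K27 between the lines gave lower values in mK4 at several named genes. Sp8 had 119 reads in mK3 and 15 in mK4 (6.44-fold lower, 3.75 to 11.9), Nkx2-3 had 89 and 12 (6.02-fold lower, 3.28 to 12.1) and Foxa1, a pioneer factor of endoderm, had 95 and 16 (4.82-fold lower, 2.82 to 8.77). Chst5, a sulfotransferase gene, was 8.52-fold lower (3.7 to 24.1). Lhx1, which is required for early nephron formation, had 110 and 35 reads (2.55-fold lower, 1.73 to 3.85), Wnt7b 99 and 33 (2.43-fold lower, 1.63 to 3.73), the Notch ligand gene Dll4 69 and 16 (3.5-fold lower, 2.01 to 6.46), the endothelial cadherin gene Cdh5 65 and 20 (2.64-fold lower, 1.58 to 4.6) and Nog 84 and 22 (3.1-fold lower, 1.92 to 5.2). Nog thus had more H3K4 and less H3K27 in mK4. Higher H3K27 in mK4 was found at Parvb (12 and 46 reads, 4.72-fold, 2.46 to 9.8), Lrp3 (11 and 49, 5.49-fold, 2.82 to 11.7), Tspan2 (38 and 168, 5.45-fold, 3.81 to 7.97) and Hoxc5 (21 and 49, 2.88-fold, 1.69 to 5.05).

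In all, H3K27 was at least 2-fold higher in mK4 at 195 of the 3614 genes marked in at least 1 line and at least 2-fold lower at 205, where counting noise gave means of 23 and 25. Choosing the marked genes against exon length gave 322 higher and 84 lower, and centring the ratios on their median gave 213 and 180. In the inputs, 526 of the same genes were higher and 390 lower. With neighbour input subtracted, 127 were higher and 159 lower, of which 50 and 89 were also called before. Of the 12 highest-ranked genes with lower H3K27, 10 passed in both forms and Gfra2 and Pcdh8 on chromosome 14 did not. Of the 12 with higher H3K27, 11 lay on chromosome 3 or 7 or in the chromosome 15 run, and 5 (Adh6-ps1, Lrp3, Parvb, Ranbp3l and Tspan2) passed in both forms. Slc45a2 and Rxfp3 in the run and Rwdd3, Adh6a, Fcgr1, Ttc24 and Fcrl5 on chromosome 3 did not. With each gene's own input subtracted, 5 of the 12 higher and 10 of the 12 lower genes passed. The log2 ratios of the others were 0.94 at Ttc24, 0.72 at Fcgr1, 0.63 at Fcrl5, 0.60 at Slc45a2, 0.58 at Adh6-ps1, 0.06 at Rxfp3, -0.70 at Ranbp3l, -0.50 at AI836003 and 0.07 at Nefl. Ranbp3l had 10 and 321 input reads and Nefl 20 and 3. Axin2, Pax9 and Fgf9, which were lower in the main comparison, did not pass with neighbour input subtracted, and Axin2 (-0.98) and Fgf9 (-0.46) did not pass with own input subtracted. Without the run and chromosomes 3, 7, 14 and X, 73 genes were higher and 167 lower.

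**Figure D3:**
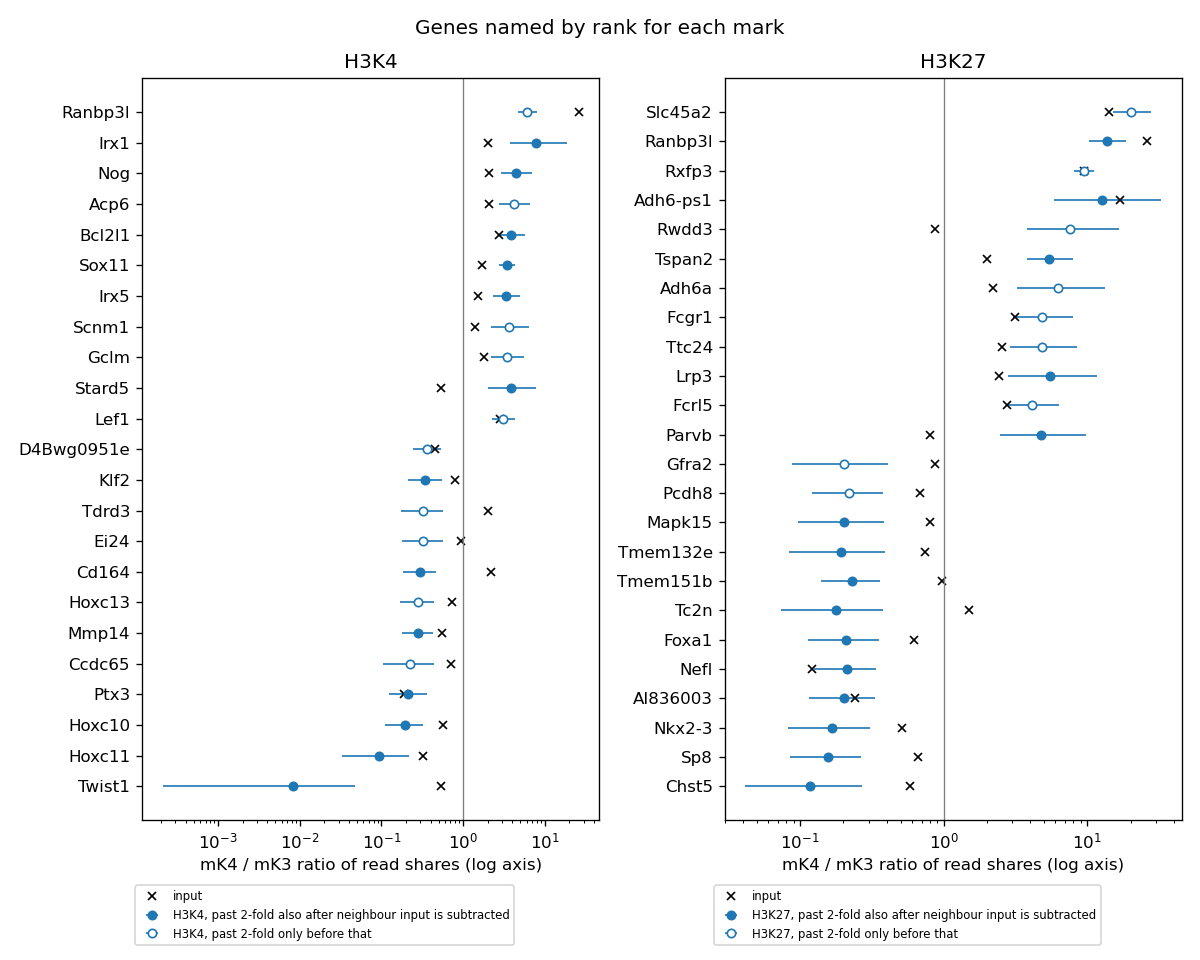
Ratio of read shares, mK4 over mK3, for the ranked genes with the largest differences in each direction for H3K4 (left) and H3K27 (right), on log axes with 95% counting intervals from 1 library per line. Crosses are the input ratios of the same genes. Filled points passed the 2-fold rule also after the neighbouring genes' input ratio was subtracted, which held for 6 of 11 H3K4-higher, 7 of 12 H3K4-lower, 5 of 12 H3K27-higher and 10 of 12 H3K27-lower genes.

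For H3K27, the nephron progenitor list had a median of -0.49 on the log2 scale (percentile 0.1), and -0.37 (percentile 0.3) with neighbour input subtracted, with no member past the rule. Its inputs lay at -0.34 (percentile 5.8), and with each gene's own input subtracted the median was -0.00 (percentile 53.4). The fixed progenitor gene Six2 had 49 and 26 H3K27 reads and Pax2 33 and 9. Renal stroma genes lay at -0.39 (percentile 1.1), at -0.12 (percentile 15.7) with neighbour input subtracted and at 0.23 (percentile 90.1) with own input subtracted. The non-renal lineage transcription factors had 4 members lower and 1 higher, at a median of -0.24 (percentile 3.0), and 2 lower and 0 higher at -0.20 (percentile 0.8) with neighbour input subtracted. Their median was -0.12 (percentile 6.7) with 5 neighbours and -0.04 (percentile 38.8) with own input subtracted. Mesenchymal genes lay at 0.11 (percentile 87.7), and at 0.27 (percentile 97.8) and 0.33 (percentile 97.1) with neighbour and own input subtracted and 0.25 (percentile 96.4) with 5 neighbours. The induced nephron list lay at 0.07 (percentile 82.3) with Lhx1 lower, but at -0.14 (percentile 9.6) with neighbour input subtracted and at -0.48 (percentile 0.4) with own input subtracted. The endothelial list lay at -0.34 (percentile 3.4, and 1.8 with quantile normalization) with Cdh5 lower, and at -0.09 (percentile 20.4) and -0.11 (percentile 28.5) with neighbour and own input subtracted. Zfp genes lay at 0.11 (reached by 0 of 10000 random lists, and percentiles 46.3 and 93.5 with neighbour and own input subtracted) and olfactory receptor genes at -0.19 (percentile 0.0), with 25 lower and 6 higher. With neighbour input subtracted, the olfactory receptor genes lay at -0.08 (percentile 10.3), with 20 lower and 14 higher, and with own input subtracted at -0.14 (percentile 0.5). Wnt ligands (-0.27, percentile 5.0) and Wnt target genes (-0.25, percentile 11.6) moved to percentiles 0.0 and 0.3 with neighbour input subtracted, and lay at -0.09 (percentile 27.6) and -0.34 (percentile 4.9) with own input subtracted. The other lists, including imprinted genes (-0.09, percentile 43.0), cell cycle inhibitors and p53 targets (-0.18, percentile 23.2), Hox genes (-0.15, percentile 24.8) and the BMP, TGF-beta and FGF ligands (-0.06, percentile 54.9), had H3K27 percentiles inside the central 95%. With own input subtracted, however, the Hox genes lay at 0.38 (percentile 99.8), the epithelial junction list at -0.45 (percentile 0.5, against -0.23 and percentile 9.4 before) and the ribosomal protein genes at 0.06 (percentile 97.9, against 46.2 before). Of the 50 medians of 25 lists and both marks, 12 lay outside the central 95% of random lists, 8 did with neighbour input subtracted and 6 with own input subtracted. By construction 2.5 of 50 unrelated random lists would, but the random lists ignore shifts that neighbouring genes share. The input medians alone lay outside for 8 of the 25 lists.

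Across the 4824 genes marked by either antibody in at least 1 line, the H3K4 and H3K27 differences between the lines correlated weakly and positively (Pearson r = 0.28, Spearman rho = 0.23). This correlation is across genes within these libraries, and genes are not independent replicates. Its differences still hold the ratios that whole chromosomes and the chromosome 15 run shared in both marks. On chromosome 3 these were 1.86 for H3K4 and 1.89 for H3K27. Such shared ratios by themselves make the differences correlate. With neighbour input subtracted r was 0.17 and with each gene's own input subtracted it was 0.73, and in either form both differences contain the same subtracted input ratio, which by itself makes them correlate.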

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

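All tests in this part were chosen after the values were seen. The input libraries, which the comparisons between lines use only as background, carried signals of their own. The run of 35 genes on chromosome 15 had an input share 8.67-fold higher in mK4 than in mK3, and it was chosen for its high input ratio. If the marks themselves had been gained over the run, the input would not have followed, but the log2 ratio of the H3K27 fold to the input fold was 0.00 and that of the H3K4 fold was -0.03. A higher copy number of the run in mK4 would also raise the ChIP libraries, on which the run was not chosen, and the lower of their folds, 8.49 for H3K4 (8.08 to 8.93), lay above the bound of 3, so more copies may be the source. Reads shared between near-identical gene copies would raise all 3 kinds of library too, but only at the copied genes. An own input log2 ratio of at least 1 was found at 33 of the 35 genes (94.3%). The run was picked on neighbouring genes with the gene itself left out, and own ratios were used only to trim its ends. Choosing on neighbours favours high own ratios but does not fix them. The share argues against reads shared at only a few copied genes as the source of the run. Its weight is limited because the choice of the run favoured it, and it cannot exclude shared reads at many of the genes. Whole-chromosome input ratios of 1.84 for chromosome 3, 1.54 for chromosome 7 and 1.49 for chromosome X were also above the mK3 level.

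Hoxa10, Hoxa11 and the overlapping antisense gene Hoxa11as, whose reads cannot be separated from those of Hoxa11 without strand, lay at 26.8 times the library mean density in the mK3 input and 16.6 times in the mK4 input, while neighbouring Hoxa9 lay at 3.96 and 2.55 times and Hoxa13 at 1.37 and 0.738 times. Among the 20 other genes densest in H3K4, input density had a median of 4.24 times the mean in mK3 and 4.63 in mK4, but reached 281 and 17 times. Input reads drawn from open, H3K4-marked chromatin stay open as an explanation, since the H3K4 density of the 3 genes was itself 40.5 and 20.3 times the mean, and in each line 4 of the 20 genes had an input to H3K4 ratio at least as high as their 0.663 and 0.816. In the H3K27 libraries, however, the 20 genes had a median density of 1.85 times the mean in mK3 and 2.32 in mK4. The 3 Hoxa genes lay at 15.4 and 9.18 times there. Extra copies of the stretch in both lines stay open as well, since they would raise every library and the lowest of the 6 densities was 9.18 times the mean, in mK4 H3K27. A transgene built on this locus, such as could have been used to immortalize the cells, is a possible source that the labels do not name and that these counts do not test.

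The H3K4 antibody's catalogue number, ab8898, belongs to an antibody sold against H3K9 trimethylation as far as is known, which conflicts with its label. If the H3K4 libraries held that mark, Zfp genes would lie high over input and ribosomal protein genes would not. The ribosomal protein genes lay at a median of at least 0.30 on the log2 scale over input in both lines (reached by at most 1 of 10000 random lists), and the Zfp genes at -0.06 and -0.00 (percentiles 21.5 and 77.4). Housekeeping genes lay near input for H3K4, at 0.05 and -0.01 (percentiles 73.2 and 58.1), so the argument rests on the other 2 lists. The ribosomal protein and Zfp values argue against H3K9 trimethylation as the target and leave the catalogue number unexplained. No biological explanation was tested for this pattern.

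In 3 named genes the mark lay at least 2-fold over input in 1 line and at least 2-fold under it in the other, and these differences were not tested. For Twist1 H3K4 over input, mK4 minus mK3 was -3.29 on the log2 scale. H3K27 over input differed by 2.53 at Rwdd3 and by 2.66 at Hoxc8, both toward mK4. Rwdd3 had 10 and 61 H3K27 reads beside 14 and 15 input reads, and did not pass with neighbour input subtracted. Hoxc8 had 38 and 43 H3K27 reads beside 49 and 10 input reads, so its difference lay mostly in the input.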

How the results depend on the processing

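No paired analysis was possible because each group has 1 library. Of 129 recomputed counts, correlations and list summaries, 74 stayed within 1.5 times the main value (or within 0.1 for the correlation) and 55 did not. Of 4256 recomputed ratios of named genes, 3695 stayed within the counting interval, 550 moved outside it and 11 changed sign. The median was 10 to 23 reads per gene, and the effect of depth on the calls was not tested. Counts of genes past a rule moved with the pseudocount and threshold, by construction of those settings. For other settings the cause was not tested.

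These settings were chosen before the data were examined. With 3-fold over input, H3K4 marked 153 genes in mK3 and 92 in mK4, H3K27 marked 493 and 365, and both marks 30 and 6. With a pseudocount of 2.5, H3K4 marked 1855 and 1439 and both marks 801 and 505, with 234 higher and 262 lower for H3K4 and 357 and 433 for H3K27. With a pseudocount of 10, H3K4 marked 433 and 343, H3K27 1201 and 1076 and both marks 58 and 16, with 33 higher and 13 lower for H3K4 and 84 and 70 for H3K27. A 1.5-fold rule gave 250 higher and 295 lower for H3K4 and 549 and 628 for H3K27, and a 3-fold rule 17, 10, 35 and 27. The filter on low values gave 54 genes lower in H3K4, 136 lower in H3K27 and 200 with both marks in mK3. Subtracting each gene's own input ratio gave 343 higher and 511 lower for H3K4, 598 and 792 for H3K27, a correlation of 0.73 and 6 list medians outside the central 95% against 12. It also turned Ranbp3l (-1.81 for H3K4 and -0.70 for H3K27) and Nefl H3K27 (0.07). Among genes with both marks in mK3 the correlation was 0.40. Median scaling, quantile normalization, median centring and the mean of a gene's rows moved none of the counts by over 1.5 times.

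The remaining settings were chosen after the data were seen. Subtracting neighbour input over 10 genes gave 127 genes higher in H3K27 and a correlation of 0.17, and turned Rxfp3 H3K27 (-0.01), Rpl39 H3K4 (-0.08) and Olfr1402 H3K27 (-0.19). With 5 neighbours no count moved by over 1.5 times, and Gclm H3K4 (-0.05), Rxfp3 H3K27 (-0.04), Fgf9 H3K27 (0.05), Rpl39 H3K4 (-0.02) and Olfr1402 H3K27 (-0.13) turned. With exon length as background, H3K4 marked 1260 genes in mK3 and 1368 in mK4, with 311 higher and 106 lower, H3K27 marked 523 and 771, with 322 higher and 84 lower, and both marks 65 and 187. For each of these 3 marked counts mK4 then lay above mK3, the opposite of the main order. Without the run and chromosomes 3, 7, 14 and X, 36 genes were higher in H3K4 and 73 in H3K27. With the input split between the marks, which lowers the input reads behind each, H3K4 marked 1815 genes in mK3 and 1432 in mK4, and the counts for H3K27 and for both marks stayed within 1.5 times. Leaving out the run alone moved no count by over 1.5 times.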

Other observations

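The tests in this part were chosen after the values were seen. The same neighbour input ratio was subtracted from the input, H3K4 and H3K27 differences between the lines, which by itself makes them correlate, so each value is given beside 100 sets of Poisson counts in which the lines differed by the neighbour input ratio alone. Over 9699 genes outside the chromosome 15 run with a mean of at least 20 scaled H3K4 counts, the input difference had a Spearman rho across genes of 0.24 with the H3K4 difference, against a mean of 0.16 and a highest value of 0.19 in the simulated sets. With the H3K27 difference rho was 0.16, against 0.15 and 0.17, so no excess was seen for H3K27. The partial correlation with H3K4 given H3K27 was 0.22 (simulated mean 0.14, highest 0.17), and that with H3K27 given H3K4 was 0.12 (0.12 and 0.14). Over the 7002 of these genes with a mean of at least 20 scaled counts for H3K27 too, rho was 0.26 for H3K4 (0.18 and 0.21) and 0.17 for H3K27 (0.16 and 0.19), at median levels of 38.2 and 36.6. These sets cover counting error only. The density of reads per exon base correlated between H3K4 and the input of the same line at rho = 0.62 in mK3 and 0.65 in mK4, and at 0.54 and 0.51 with the input of the other line. H3K27 correlated with the input of its own line at 0.33 and 0.34, and with that of the other line at 0.23 and 0.24. The nuclear noncoding RNA genes Malat1 and Neat1 lay at 4.24 and 4.47 times the library mean density in the mK3 input and at 11.4 and 13.3 times in mK3 H3K4. Col1a1, a collagen gene of mesenchymal cells, had 164 and 47 H3K4 reads in mK3 and mK4 beside 70 and 32 input reads and was marked in neither line.

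In mK3, 4 of 39 Hox genes were marked by H3K27, against 11 of 39 in mK4. The H3K27 values themselves had a median difference of -0.15 on the log2 scale (percentile 24.8), with 1 gene higher and 0 lower, while the inputs had one of -0.58 (percentile 0.0). Hoxc11 and Hoxc13 were marked by H3K4 but not H3K27 in mK3 and by H3K27 but not H3K4 in mK4. Their H3K27 reads were 16 and 14 at Hoxc11 and 37 and 39 at Hoxc13, beside input reads of 5 and 2 and of 12 and 11. Ptx3 had the same sequence of calls, with 17 and 16 H3K27 reads and 17 and 4 input reads. Without pseudocount its H3K4 fold over input, given above, was not lower in mK4, so the loss of its H3K4 call rests on the pseudocount.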
